A study of Rattus norvegicus with 12 samples.

How the data were processed

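The series holds 12 one-colour arrays of fetal Wistar rat pituitaries taken at gestational day 18. The labels place them in 4 groups of 3: male control, male TCDD, female control and female TCDD. TCDD is 2,3,7,8-tetrachlorodibenzo-p-dioxin, a dioxin that binds the aryl hydrocarbon receptor. The labels give neither its dose nor the day of dosing, and they do not say whether an array holds 1 pituitary or a pool, or which fetuses shared a litter. The p-values therefore measure the spread between these samples, and litter mates counted as separate samples would make them too small.

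Per the labels' protocols, total RNA was amplified and labelled with Cy3 and hybridised to a whole rat genome oligonucleotide array. The deposited scanner files hold spot intensity values on a linear scale, and per the file headers they were written by Agilent Feature Extraction 10.7.1.1. The submitters' processing notes name version 9.5.1.1 of the same program. The background-corrected processed intensity was used, together with the flags that the authors deposited beside it (well above background, saturated, outlier among pixels, outlier among replicate spots). Probe positions are on the rn4 build, per the file headers. The authors' deposited value table also holds intensity values. Each of its columns had a median of 83.5 and a Spearman correlation of 1.0 with the scanner values of the same array, so its scale was taken as linear intensity after quantile normalization between arrays. That step was inferred from the equal distributions, since no source used here states it. Scale and centring were thus found from the values, and one-colour values have no direction to settle.

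Control spots and spots flagged as outliers were left out. The log2 of the processed intensity was taken, the 75th percentile of each array was subtracted, and spots of a probe were averaged. Levels below are on this scale, log2 relative to the array's 75th percentile, and levels of different probes are not compared. A probe was kept if it was well above background on at least 3 of the 12 arrays and had at least 10 values. Of 30367 probes, 22431 were kept. Each gene was read from its brightest kept probe, which gave 19357 genes, 16570 of them with 1 kept probe. Through the reference table of gene names, 18006 probes were named by accession and 2654 by symbol, and 9707 kept the name in the files. Each array had 42877 spots that were not controls, and between 75.1% and 78.4% of these spots lay well above background. No spot was saturated, and the 75th percentile of an array lay between 9.87 and 10.29 on the log2 scale. The median coefficient of variation of replicate spots within an array lay between 3.58% and 4.31%. The number of arrays limits the precision.

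Comparisons were fitted with limma 3.58.1 in R 4.3.3, on all 12 arrays with a mean for each group, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over 19357 genes. A gene was called at an adjusted p below 0.05. The comparisons were TCDD against control in males, in females and over both sexes (the mean of the effects in males and females), the difference of the TCDD effect between the sexes, and male against female controls. All adjusted p-values of genes come from these limma fits. A probe that was not well above background on any array of a group has only a bound there. Its difference is given as at least N-fold, from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

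There were 28 gene lists fixed before the data were examined. They cover the aryl hydrocarbon receptor battery, pituitary cell types and development, other tissues that a dissected pituitary could carry, stress, metabolism, and sex-linked genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 28 lists of a comparison. Only genes with a value on every array entered, which leaves out Pomc. Counts within a list are given over all genes and adjusted over the list alone. A further 3 lists, of sensory ganglion neuron, peripheral glia and forebrain neuron markers, were written after the arrays were seen, and so was a list of 17 heart muscle markers, 10 of them measured, for 1 test.

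The named genes followed a rule fixed before the data were examined. Where 5 or more genes passed, it takes up to 10 higher and 10 lower genes with the largest change among those that have a gene symbol and non-overlapping groups. Where fewer passed, it takes the 10 genes with the smallest unadjusted p, given as values. It adds list members that passed, up to 4 for a list, and for the difference between sexes up to 10 genes with the smallest p. For exposure it always names Cyp1a1, Cyp1b1, Ahrr, the Tiparp transcript, Nqo1, Ahr, Gh1, Prl, Pomc, Tshb, Lhb, Fshb, Cga and Gnrhr. List members that did not pass are examples chosen after their values were seen. Results on some genes are not reported here. The alternatives were another background correction, other normalizations, the authors' value table, other filters, other ways from probe to gene, other variance models, array weights, slide or replicate number as a block, and leaving out each replicate. The other background correction was normexp with an offset of 50 added to every intensity. That offset by itself shrinks log2 differences of dim signals. The fits without variance moderation used only the arrays of the groups compared, so within a sex and between controls they also changed the arrays fitted. After the arrays were seen, fits with the ganglion marker mean as a covariate, without the arrays that carry it, and within slides were added.

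The 12 arrays lay on 3 slides, each scanned once. Slide 1 held male control 1 to 3 and male TCDD 1. Slide 2 held male TCDD 2 and 3 and female control 1 and 2. Slide 3 held female control 3 and female TCDD 1 to 3. Slide and group are thus partly confounded. With slide as a fixed block the effect in males rests on the array of male TCDD 1 against its 3 controls, and the effect in females rests on the array of female control 3. Whether replicate numbers pair samples was checked by the correlation of deviations from the group means. Between male and female controls the 3 same-numbered pairs correlated at 0.13, 0.75 and 0.35, all above 0.1, so the numbers were treated as pairing those samples. This pairing is an assumption. Male control 1 correlated more with a female control of another number (0.35), and both arrays of pair 2 carried the ganglion signal described below. The pairs of the other groups did not all reach 0.1, the lowest being -0.70.

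The fit was tested on simulated data built from the gene means and residual spreads of the real arrays, with independent noise and a seeded set of changed genes among 19325. For TCDD against control in males it recovered 67.2% of genes changed 2-fold, 82.1% at 4-fold and 90.9% at 8-fold, with 6 false calls among 166. In females it recovered 58.2% at 2-fold and over both sexes 65.7%. For the difference of the TCDD effect between sexes it recovered 29.9% at 2-fold and 84.8% at 8-fold. The simulated noise leaves out the shared variation between arrays described in the report. In each comparison 67 genes were changed 2-fold, 67 were changed 4-fold and 66 were changed 8-fold, while the real fit in males called 2 genes. With more calls the Benjamini-Hochberg adjustment lets larger p-values pass. These shares therefore overstate the recovery where only a few genes change.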

Results

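The pituitaries of control and TCDD-exposed fetuses were compared by whole-genome expression array in both sexes, with 3 arrays in each of 4 groups. The question stated by the series title is how maternal dioxin exposure affects pituitary mRNAs at gestational day 18. Between any pair of arrays the correlation over genes lay between 0.94 and 0.99. The first principal component held 53.0% of the variance and was positive on the same 6 arrays in which genes of sensory ganglion neurons were high. The mean of 25 measured ganglion neuron markers lay between -1.08 and 0.31 on 6 arrays and between -4.89 and -4.40 on the other 6. The 6 arrays with the higher level were male control 2, male TCDD 1 and 2, female control 2, and female TCDD 1 and 3. They thus made up 4 of the exposed arrays and 2 of the control arrays, so this signal moved in part with exposure (mean difference 1.47 on the log2 scale). These markers were chosen after the arrays were seen. Male TCDD 1 stood apart from the other arrays, with the highest ganglion mean (0.31), a first principal component of 90.0 against 47.2 for the next array, and the vasopressin gene Avp at -1.86 against -6.24 to -5.58 on the other 11. All values in males within slide 1 or with slide as a fixed block rest on this array.

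**Figure D1:**
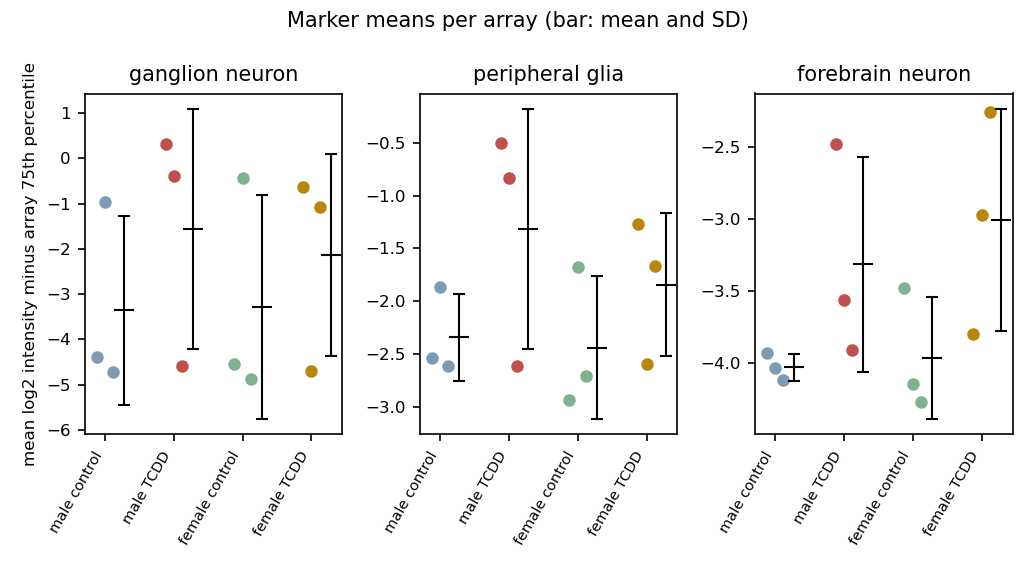
Mean level of sensory ganglion neuron, peripheral glia and forebrain neuron markers on each array (log2 intensity relative to the array's 75th percentile), with points for arrays and bars for the group mean and SD (n = 3). Ganglion neuron markers fell into arrays near -4.40 or lower and arrays at -1.08 or higher in every group.

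In males, TCDD exposure was accompanied by a large rise of 2 genes. Ahrr, which encodes a repressor of the aryl hydrocarbon receptor, stood at -5.74 ± 0.51 in male controls and 0.24 ± 0.34 in exposed males (SD, n = 3), a 63.1-fold rise (log2 5.98, standard error 0.36, adjusted p = 0.000155). Cyp1a1, a cytochrome P450 that is the classical target of that receptor, was not well above background in any control and was at least 27.1-fold higher in exposed males (measured means -7.59 ± 0.46 and -1.83 ± 0.65, adjusted p = 0.000266). All 3 exposed males lay above all 3 controls for both genes. The probe of Ahrr lies on rn4 chromosome 1 from 29894853 to 29894912, and that of Cyp1a1 on chromosome 8 from 61468133 to 61468192.

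The limma fit called 2 genes higher and 0 lower in males among 19357, and 1821 genes had an unadjusted p below 0.05, where 968 are expected by chance. The groups did not overlap for 14.5% of genes, where chance gives 10%. The next genes by p did not pass. They were Nqo1, a quinone reductase (log2 1.38, adjusted p = 0.0644), the tight junction gene Cldn14 (log2 2.43, adjusted p = 0.0711), Ihh, which encodes the signal Indian hedgehog (log2 2.04, adjusted p = 0.0831), XM_216321 (log2 0.84), RGD1564463 (log2 1.76), ENSRNOT00000032067 (log2 0.73), the unnamed probe A_64_P086859 (log2 0.64) and Gpihbp1, a lipoprotein lipase anchor (log2 -1.44). The last 5 had adjusted p-values between 0.17 and 0.182. In the fit with slide as a fixed block, and equally within slide 1, Ahrr differed by 5.84 on the log2 scale, and within slide 1 Cyp1a1 was at least 17.1-fold higher. The blocked fit called 27 genes and the fit within slide 1 called 277, both resting on the array of male TCDD 1. Normexp background correction, whose offset shrinks differences of dim signals, gave a difference of 3.86 for Ahrr. It gave a fitted 2.35 for Cyp1a1, which then did not pass the threshold. The count was 1 gene with normexp background correction, with the males alone and with probes well above background on all 12 arrays, and 4 without the variance trend and with the ganglion marker mean as a covariate. It was 0 in limma without variance moderation (1342 at an unadjusted p below 0.05) and without the 6 arrays that carried the ganglion signal (939), where Ahrr still differed by 5.97, and 6543 with array quality weights, which gave male TCDD 2 a weight of 12.9 and no other array more than 2.12.

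In females the same 2 genes rose. Ahrr stood at -5.64 ± 0.59 in controls and 0.22 ± 0.45 in exposed females (SD, n = 3), a 58.1-fold rise (log2 5.86, standard error 0.36, adjusted p = 0.00019). Cyp1a1 was at least 24.0-fold higher in exposed females (measured means -7.39 ± 0.16 and -1.92 ± 0.63, adjusted p = 0.000442), and was not well above background in any female control. For both genes all 3 exposed females lay above all 3 controls.

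The female count was 2 higher and 0 lower, with 511 genes at an unadjusted p below 0.05 against 968 expected by chance, and groups that did not overlap for 6.96% of genes. The other genes of smallest p did not pass: Ihh (log2 2.07, adjusted p = 0.121), Nqo1 (log2 1.20, adjusted p = 0.168), LOC682360 (log2 -1.04), Cyp1b1, another cytochrome P450 induced through the same receptor (log2 1.03), Dapl1 (log2 -0.96), the ATP-gated channel gene P2rx2 (log2 -0.47), the basal keratin Krt5 (log2 -1.17) and the cell cycle inhibitor Cdkn2b (log2 -1.11). Within slide 3, where 3 exposed females stood against the array of female control 3, Ahrr differed by 6.01 on the log2 scale and Cyp1a1 was at least 26.1-fold higher, and 0 genes passed in limma (528 at an unadjusted p below 0.05). The blocked fit gave the same difference for Ahrr and called 2 genes. Normexp background correction gave 3.79 for Ahrr and a fitted 2.20 for Cyp1a1, which then did not pass the threshold. The count was 1 with normexp background correction and with probes well above background on all 12 arrays, and 0 in limma without variance moderation (569 at an unadjusted p below 0.05) and without the 6 arrays that carried the ganglion signal (488), where Ahrr differed by 6.64 with fewer arrays.

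Over both sexes 4 genes rose and 0 fell. Ahrr rose 60.5-fold (log2 5.92, standard error 0.25, adjusted p = 5.27e-06), and Cyp1a1 was at least 25.5-fold higher (adjusted p = 1.08e-05). Nqo1 rose 2.44-fold (log2 1.29, standard error 0.12, adjusted p = 0.00406), from -4.30 ± 0.19 to -2.92 ± 0.14 in males and from -4.21 ± 0.23 to -3.01 ± 0.24 in females (SD, n = 3). Ihh rose 4.16-fold (log2 2.06, standard error 0.20, adjusted p = 0.00406), from -2.89 ± 0.38 to -0.84 ± 0.32 in males and from -2.93 ± 0.54 to -0.86 ± 0.15 in females (SD, n = 3). All exposed arrays lay above all controls of their sex for these 4 genes. The calls of Nqo1 and Ihh were lost with the replicate block of the number, as given below with the other alternatives. The probe of Nqo1 lies on rn4 chromosome 19 from 37251727 to 37251786, and that of Ihh on chromosome 9 from 74287130 to 74287189. A further Ihh probe, well above background on 1 array, differed by 2.23 in males and 0.10 in females.

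**Figure D2:**
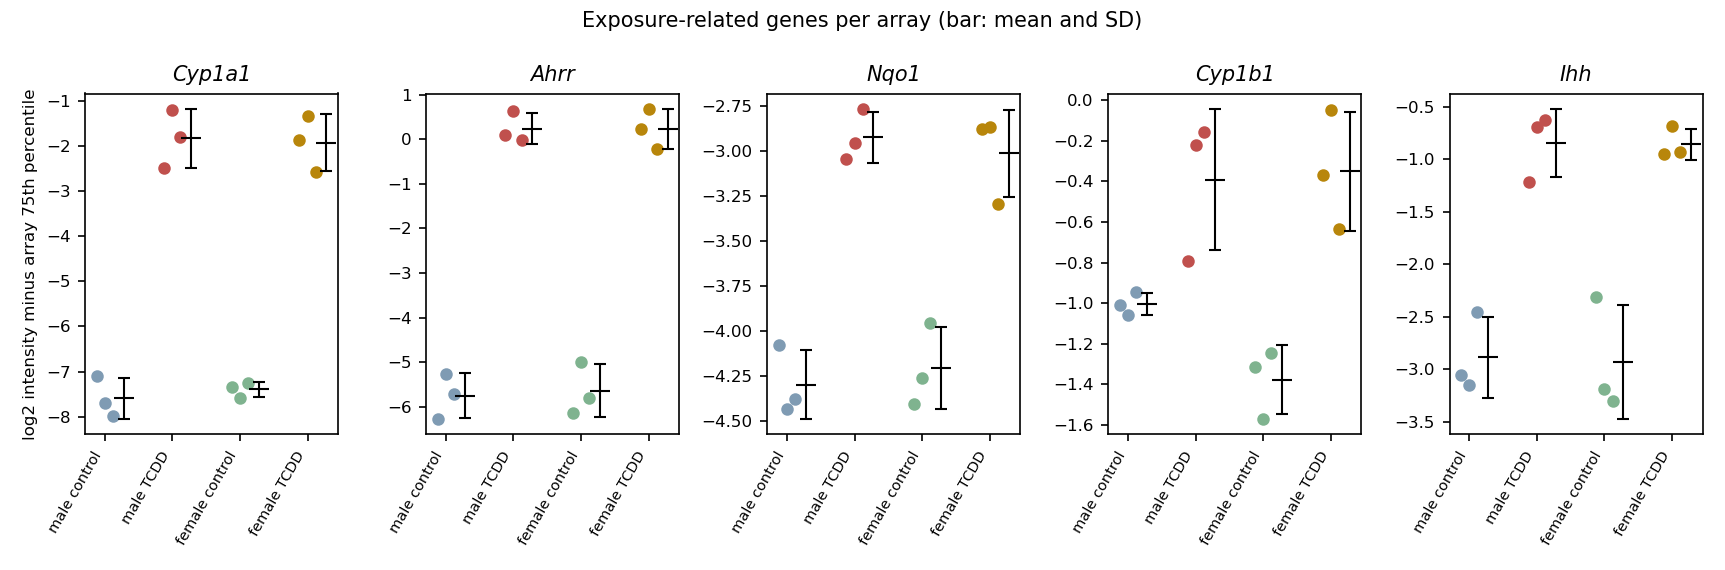
Levels of Cyp1a1, Ahrr, Nqo1, Cyp1b1 and Ihh on each array (log2 intensity relative to the array's 75th percentile), with points for arrays and bars for the group mean and SD (n = 3). Exposed arrays lay above the controls of the same sex for all 5 genes, of which Cyp1b1 did not pass the threshold over both sexes (adjusted p = 0.111).

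Among 18 measured genes of the aryl hydrocarbon receptor battery, 3 passed over all genes, all higher, and 7 were higher when adjusted over the list alone. The 7 were Ahrr, Cyp1a1, Nqo1, Cyp1b1 (log2 0.82), the glucuronosyltransferase Ugt1a6 (log2 0.39), Nfe2l2 (log2 0.32), which encodes the antioxidant regulator Nrf2, and the aldehyde dehydrogenase Aldh3a1 (log2 0.60). The list's mean difference was 0.57 but its median was -0.004, with 9 members above 0 and 9 below. Camera gave it an adjusted p of 0.00346, and the adjusted p was 0.773 with an estimated correlation. Fry, which asks whether the list moves one way without setting it against other genes, gave an adjusted p of 0.0147. When slide was a block the mean was 0.28, with 0.14 in males within slide 1 and 0.42 in females within slide 3. The receptor gene Ahr itself differed by -0.27 (adjusted p = 0.67). The transcript ENSRNOT00000015387, described in the files as a TCDD-inducible poly(ADP-ribose) polymerase, differed by 0.50 (adjusted p = 0.265) and was higher in all exposed arrays than in the controls of their sex.

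Over both sexes 1247 genes had an unadjusted p below 0.05, where 968 are expected by chance. The rest of the 10 genes with the smallest p were values short of the threshold: LOC682360 (log2 -0.97), Gpr97 (at least 1.14-fold higher, controls not well above background), the myosin heavy chains Myh7 (log2 1.38, adjusted p = 0.0694) and Myh6 (log2 1.48, adjusted p = 0.079), Cldn14 (log2 1.56) and Dapl1 (log2 -0.90). A fit with slide as a fixed block called 14 genes, 3 of them among the 4 above, with Ahrr at 5.93 and Ihh at 2.06 on the log2 scale and an adjusted p of 0.0872 for Nqo1, array quality weights called 197, and the ganglion marker mean as a covariate gave 11, the 4 above, Myh6 and Myh7 included. Normexp background correction gave differences of 3.82 for Ahrr, 0.74 for Nqo1 and a fitted 2.28 for Cyp1a1, all past the threshold. Without the 6 arrays that carried the ganglion signal 0 genes were called (542 at an unadjusted p below 0.05), although the differences were 6.30 for Ahrr, 1.39 for Nqo1 and 2.12 for Ihh and so did not shrink. With the replicate block of the number Nqo1 and Ihh did not pass, at unchanged differences (adjusted p = 0.0507 for both, with a range over the alternatives of 0.0012 to 1.0 for Nqo1 and 0.000926 to 1.0 for Ihh). The count was 9 without male TCDD 1, 7 without male TCDD 3 and 7 without female control 1.

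No hormone gene passed the threshold in the fit of group means. Gh1, which encodes growth hormone, stood at -0.89 ± 1.39 in male controls, -3.46 ± 0.95 in exposed males, -1.06 ± 0.90 in female controls and -3.25 ± 1.27 in exposed females (SD, n = 3). Its difference over both sexes was -2.38 with a standard error of 0.59 (adjusted p = 0.594), and 5 of the 6 exposed arrays lay below every control. The ganglion signal was present on 4 of the 6 exposed arrays and on the 2 controls with the lowest Gh1 (-2.45 in male control 2 and -2.10 in female control 2), while the other 4 controls lay between -0.61 and 0.17. Ghrhr, the gene of the growth hormone-releasing hormone receptor, was also lowest among controls on these 2 arrays (-5.92 and -6.23, against -4.53 to -4.02), while Tshb and Cga were lowest on male control 1. The difference of Gh1 was -1.98 with the ganglion marker mean as a covariate and -2.92 without the 6 arrays that carried the signal. An exact permutation of exposure within each sex, chosen after the values were seen and 2-sided over 400 arrangements, gave p = 0.015 for Gh1, and 0.0263 after adjustment over the 7 values tested so. The smallest p these arrangements allow is 0.005. With same-numbered male and female controls kept together, 56 arrangements gave an exact p of 0.0714, where the smallest possible is 0.0357. Within slide 1 Gh1 differed by -3.51 in males, within slide 3 by -2.79 in females, and with slide as a block by -3.15. The other hormone genes, over both sexes, differed by -1.26 for Fshb, -0.76 for Tshb, -0.58 for Lhb, -0.50 for Cga, -0.31 for Pomc and 0.02 for Prl, with adjusted p-values between 0.669 and 0.983. The mean of Tshb, Cga and the transcription factor gene Pou1f1 differed by -0.57, with 5 exposed arrays below every control. Its exact permutation p was 0.015, and 0.0263 after the same adjustment over 7 values. With control pairs kept together the exact p was 0.0357, the smallest possible. Fshb was not well above background on 4 of the 12 arrays, and its difference was -0.29 with normexp background correction. The gonadotropin-releasing hormone receptor gene Gnrhr differed by -0.75 (adjusted p = 0.67). Tshb passed over both sexes with slide as a fixed block (log2 -1.06) and with array quality weights (log2 -0.70). In males Tshb passed in the same fits, and Gh1, Fshb, Lhb and Gnrhr with array quality weights. That weighted fit called 6543 of 19357 genes in males and gave male TCDD 2 a weight of 12.9. A pass in it was thus shared by a large part of all genes. Within slide 1, where male TCDD 1 was the only exposed array, Tshb differed by -1.55 and Cga by -1.39. Without the 6 arrays that carried the ganglion signal the differences in males were near 0 or turned for Tshb (-0.07), Lhb (-0.0085), Cga (0.09), Pomc (0.07) and Gnrhr (0.32), while Gh1 differed by -2.40 and Fshb by -0.50. Over both sexes the differences without these arrays were -0.44 for Tshb, -0.26 for Lhb, -0.16 for Cga and -0.33 for Gnrhr. With slide as a fixed block, which rests on male TCDD 1 and female control 3, they were -1.22 for Lhb, -0.93 for Cga and -1.17 for Gnrhr. The sign of Prl turned with median centring (-0.0054) and with slide as a block (-0.62).

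**Figure D3:**
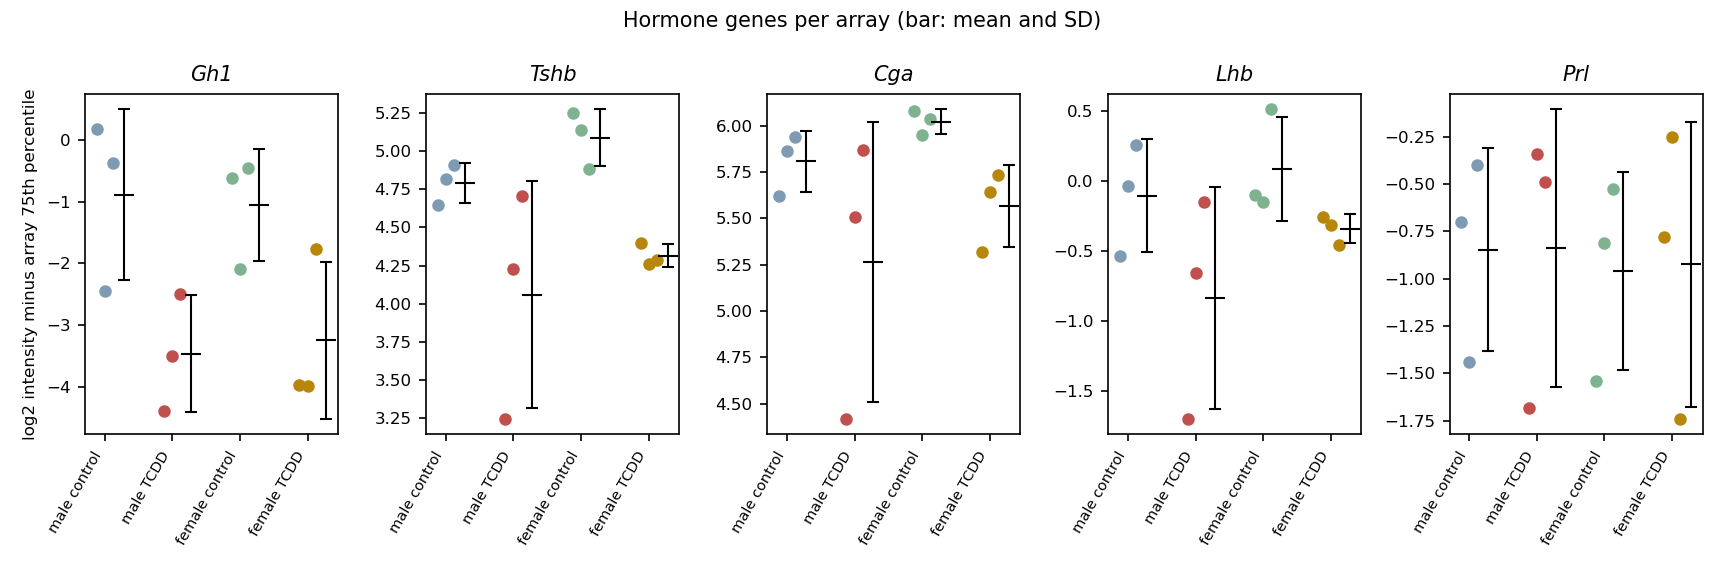
Levels of Gh1, Tshb, Cga, Lhb and Prl on each array (log2 intensity relative to the array's 75th percentile), with points for arrays and bars for the group mean and SD (n = 3). Mean Gh1 was -0.89 and -1.06 in the control groups and -3.46 and -3.25 in the exposed groups, and none of the 5 genes passed the threshold.

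Of 13 measured genes of the somatotrope, lactotrope and thyrotrope list, 0 passed over all genes, and adjusted over the list alone 2 were higher and 4 lower. The higher were the somatostatin receptor gene Sstr2 (log2 1.11) and the retinoid receptor gene Rxrg (log2 0.49), and the lower were Gh1, Tshb, the deiodinase gene Dio2 (log2 -0.79) and Ghrhr (log2 -1.88). Ghrhr lay at -9.07 in male TCDD 1 and -7.01 in female TCDD 2. Both levels are below the lowest signal of spots well above background on those arrays, so its difference rests in part on values at background. The list's mean difference of -0.33 did not pass camera (adjusted p = 0.58). The gonadotrope list passed camera as lower (adjusted p = 0.00346, mean -0.31, 14 of 18 members below 0), with 0 members past the threshold over all genes and 1, the secretory granule gene Chgb (log2 -0.51), adjusted over the list alone. Its adjusted p was 0.773 with an estimated correlation. The mean of the gonadotrope genes was -0.54 with slide as a block, -0.79 in males within slide 1, which rests on male TCDD 1, and -0.30 in females within slide 3. It was -0.0849 and did not pass without the 6 arrays that carried the ganglion signal. In the pituitary progenitor list, where camera gave an adjusted p of 0.163, examples are the homeobox genes Lhx3 (log2 -0.37) and Lhx4 (log2 -0.60), neither of which passed.

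Among lists of other tissues, skeletal muscle markers were lower over both sexes by camera (adjusted p = 6.93e-05, mean -0.43, 16 of 16 members below 0), and the adjusted p was 0.773 with an estimated correlation. Examples are the troponin gene Tnni1 (log2 -0.59), the myosin light chain gene Myl1 (log2 -0.75) and Myod1 (log2 -0.74), a regulator of muscle identity, none past the threshold. Cholesterol synthesis genes were higher by camera (adjusted p = 0.00346, mean 0.25, 20 of 22 members above 0), with an adjusted p of 0.773 with an estimated correlation. Of these, Acat2 differed by 0.36, Dhcr7 by 0.37 and Lss by 0.49, none past the threshold. The mean of the cholesterol synthesis genes was 0.0076, with a camera direction of lower, when the ganglion marker mean was a covariate, and -0.0683 without the 6 arrays that carried the ganglion signal. Circadian clock genes were lower by camera (adjusted p = 0.0404, mean -0.17, 16 of 19 members below 0), with Nr1d1 at -0.50 and Dbp at -0.28, and the adjusted p was 0.773 with an estimated correlation. In males within slide 1 and females within slide 3 the means were -0.66 and 0.05 for skeletal muscle, 0.94 and 0.40 for cholesterol synthesis, and -0.47 and -0.30 for clock genes, and the blocked means over both sexes were -0.30, 0.67 and -0.39. No other of the 28 lists passed camera over both sexes. The count of 5 lists became 8 without male control 1 and 3 without female control 3.

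The lists were also tested in each sex, where camera called 6 of 28 in males and 13 in females, and 0 in either with an estimated correlation (smallest adjusted p = 0.922 in males and 0.272 in females). In males the called lists had means of -0.62 for skeletal muscle, -0.34 for immune cells, -0.27 for endothelium, -0.26 for mesenchyme, -0.32 for gonadotropes and 0.42 for cholesterol synthesis. In females oral epithelium markers had a mean of -0.67 with 7 of 8 members below 0, and 3 of them, Krt5, Lgals7 (log2 -1.80) and Perp (log2 -0.61), were lower when adjusted over the list alone. Cartilage and bone markers had a mean of 0.35 with 15 of 15 members above 0. Within slide 3 these means were -0.89 and 0.18. The other called lists of one sign in both fits were the aryl hydrocarbon receptor battery (0.63, and 0.42 within slide 3), posterior lobe and neuron markers (0.51 and 1.06), mesenchyme (0.24 and 0.02), heat shock genes (-0.13 and -0.17), clock genes (-0.21 and -0.30) and gonadotropes (-0.30 and -0.30). The sign turned within slide 3 for corticotropes (-0.27 to 0.04), erythroid cells (0.11 to -0.39), immune cells (0.12 to -0.26), endothelium (0.17 to -0.06) and Nrf2 antioxidant genes (0.05 to -0.11). Single arrays also turned it, with means of -0.0274, -0.0029 and -0.0875 for erythroid markers without female control 1, female control 2 and female TCDD 2, of -0.0213 and -0.039 for immune cell markers without female control 2 and female TCDD 2, and of -0.0123 for Nrf2 antioxidant genes without female control 1. Within slide 1, where male TCDD 1 was the only exposed array, the means in males were -0.66 for skeletal muscle, -0.76 for immune cells, -0.54 for endothelium, -0.65 for mesenchyme, -0.79 for gonadotropes and 0.94 for cholesterol synthesis. Without the 6 arrays that carried the ganglion signal the sign turned in males for gonadotrope genes (0.0873), mesenchyme and fibroblast markers (0.073) and cholesterol synthesis genes (-0.0142), and the mean was -0.0844 for immune cell markers. In females the means without these arrays were 0.16 for posterior lobe, hypothalamus and neuron markers and 0.0262 for Nrf2 antioxidant genes, neither of which then passed, and 0.39 for erythroid markers, 0.29 for immune cell markers and 0.39 for mesenchyme and fibroblast markers. The male count became 2 without male control 3 and 2 without male TCDD 1, and the female count 7 without female TCDD 2.

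**Figure D4:**
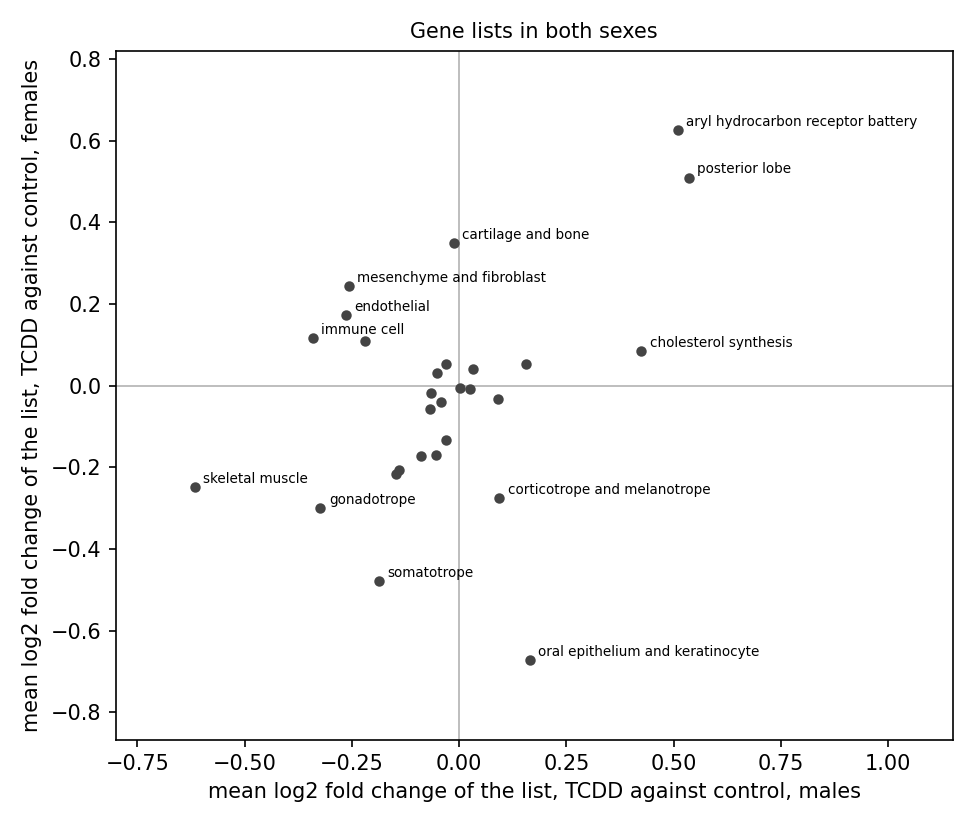
Mean log2 fold change of each of the 28 gene lists, TCDD against control, in males (horizontal axis) and in females (vertical axis), 1 point for a list and no error drawn. The aryl hydrocarbon receptor battery lay at 0.51 and 0.63, skeletal muscle at -0.62 and -0.25, and oral epithelium at 0.17 and -0.67.

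The difference of the TCDD effect between males and females called 0 genes in the limma fit, with 866 at an unadjusted p below 0.05, where 968 are expected by chance. Without variance moderation the same contrast called 0 genes, with 985 at an unadjusted p below 0.05. The genes of smallest p, none of which passed (adjusted p = 0.88 for all 10), were ENSRNOT00000032067 (difference of log2 effects 1.06), A_64_P086859 (0.77), A_64_P122755 (0.64), XM_216321 (0.97), ENSRNOT00000032908 (1.16), A_64_P130795 (0.81), Ywhaq (0.63), A_64_P080603 (1.12), XM_228468 (1.39) and the kinase gene Stk32a, which was not well above background in male controls or exposed females and is given no difference. Slide as a fixed block gave 6 called genes. For Gh1 the difference was -0.39 with a standard error of 1.17. Camera called 7 lists, and 0 with an estimated correlation (smallest adjusted p = 0.935), and it called 11 lists without male TCDD 3.

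Between male and female controls 2 genes, both X-linked, were lower in males. LOC680227, whose probe lies on rn4 chromosome X from 91462945 to 91463004, was not well above background in any male and at least 3.10-fold lower in male than in female controls (measured means -8.42 ± 0.11 and -4.96 ± 0.11, SD, n = 3, adjusted p = 0.000562). Eif2s3, an X-linked translation initiation factor gene, fell from 2.55 ± 0.04 in female controls to 1.87 ± 0.04 in male controls (SD, n = 3, log2 -0.68, standard error 0.06, adjusted p = 0.0035), and a further Eif2s3 probe differed by -0.97. In the list of X genes that escape inactivation, with 7 measured members, 1 passed over all genes and 3 were lower adjusted over the list alone, namely Eif2s3, Pbdc1 (log2 -0.52) and the helicase gene Ddx3x (log2 -0.32). A further Ddx3x probe, well above background on all 12 arrays, differed by -0.0955. Camera gave the list an adjusted p of 0.00146, and the adjusted p was 0.285 with an estimated correlation. The only measured Y-linked gene, Sry, differed by 0.04 (adjusted p = 1.0), so its probe did not separate the sexes.

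The count between control sexes was 2 lower and 0 higher in males, with 1066 genes at an unadjusted p below 0.05 against 968 expected by chance. Other genes of smallest p, beside Pbdc1 and Ddx3x, did not pass and were A_64_P122755 (log2 -0.46), AA926063 (at least 1.83-fold lower in males), RGD1564463 (log2 -1.45), A_64_P134553 (log2 -1.35), ENSRNOT00000032067 (log2 -0.79) and XM_216321 (log2 -0.79). RGD1564463, ENSRNOT00000032067 and XM_216321 were also among the smallest p of exposure in males, a comparison that uses the same male controls. Replicate numbers were treated as pairing these samples. With a replicate block of treatment and number 0 genes were called in limma (950 at an unadjusted p below 0.05), at the same differences (adjusted p = 0.16 for LOC680227). The fit with slide as a fixed block called 10 genes, 0 of them shared with the 2 above, with Eif2s3 at -0.71 and an adjusted p of 0.124 for LOC680227, and no slide held both control groups. Normexp background correction, under which LOC680227 had a fitted difference of -0.56 and did not pass, called 1 gene, and 0 were called in limma with the control groups alone (1106 at an unadjusted p below 0.05), without variance moderation (1042) and without the 6 arrays that carried the ganglion signal (788). Ribosomal protein genes had a mean of -0.20 (camera adjusted p = 0.00146, and 0.996 with an estimated correlation), which was 0.08 with slide as a block. Immune cell markers had a mean of 0.20 (camera adjusted p = 0.00417, and 0.996 with an estimated correlation), and 1.01 with slide as a block.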

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

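The tests on ganglion genes, Gh1 and the myosin genes were chosen after the result was seen, as were the splits and permutations that keep control pairs together, and the list tests and the other counts over splits of the arrays were planned.

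Camera, at its preset correlation, found that 7 gene lists differed in their TCDD effect between the sexes, while with an estimated correlation none of the 28 lists passed (smallest adjusted p = 0.935). The values are given here as the mean log2 effect in males minus that in females. These were endothelial markers (-0.44), immune cell markers (-0.46), mesenchyme and fibroblast markers (-0.50), skeletal muscle markers (-0.37), cartilage and bone markers (-0.36), erythroid markers (-0.33) and oral epithelium and keratinocyte markers (0.84). With slide as a block the differences were -0.48, -0.50, -0.67, -0.71, -0.17, -0.12 and 1.59 in the same order, and without the 6 arrays with the ganglion signal -0.27, -0.37, -0.32, 0.0784, -0.84, -0.42 and 0.29, so that the sign turned for skeletal muscle markers.

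Sensory ganglion neuron genes were high on 6 of 12 arrays, with a gap of 3.32 on the log2 scale to the other 6. All 3 slides held arrays of both kinds, which argues against slide as the source. Exposure as the only source is excluded by the 2 control arrays with the signal, and an exact permutation of the ganglion marker mean over exposure, 2-sided, gave p = 0.27. Peripheral glia markers, also listed after the arrays were seen, were higher on the same 6 arrays (means of -1.86 to -0.50, against -2.93 to -2.54 on the other 6). The source of the signal stays open, and a difference in dissection between the groups was not tested.

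Gh1 was lower in exposed arrays, and among controls it was lowest in the 2 arrays with the ganglion signal (-2.45 in male control 2 and -2.10 in female control 2, against -0.61 to 0.17 in the other 4). An even dilution by ganglion tissue would lower pituitary transcripts alike. The mean of Tshb, Cga and Pou1f1 itself differed by -0.57. The difference of Gh1 lay -1.81 on the log2 scale from it (exact permutation p = 0.025, 2-sided). With same-numbered control arrays kept together this exact p was 0.143, so the test does not settle dilution. On arrays without the ganglion signal Gh1 was -2.50 in male TCDD 3 and -3.99 in female TCDD 2, against -0.61 to 0.17 in controls. These values argue against dilution by ganglion tissue for these 2 exposed arrays, 1 of each sex, and leave it open for the others. A link of Gh1 with the ganglion signal stays open, with a difference of -1.98 with the ganglion marker mean as a covariate and -2.92 without the 6 arrays that carry it. Slide cannot be told apart, since the difference of -3.15 with slide as a block (standard error 0.83) rests on 1 exposed male and 1 female control. An exact permutation over exposure gave p = 0.015, and 0.0714 with the control pairs kept together, so exposure stays open beside fetal maturity and litter, which were not tested, and the genome-wide adjusted p was 0.594.

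Myh6 and Myh7 were higher in all 6 exposed arrays than in every control. Skeletal or heart muscle in the dissected piece would bring its other transcripts, but 0 of 16 skeletal muscle markers had a positive difference, and 1 of 7 heart muscle markers well above background on every array did (Ryr2, 0.15), 1 of the 7 being in both lists. A single signal read by near-identical myosin probes could not be settled: Myh13, named after its values were seen, differed by 1.60 at its brightest probe and by -0.68 at its other probe, which was well above background on 7 arrays only. An effect of TCDD exposure stays open, since over all genes the adjusted p was 0.079 for Myh6 and 0.0694 for Myh7, with a range over the alternatives of 0.00396 to 1.0 and of 0.00269 to 1.0. Both genes passed with array quality weights, with the ganglion marker mean as a covariate (log2 1.60 and 1.49), without male TCDD 1 and without female control 1.

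Other splits of the same arrays were counted for each comparison. In males 1 of 10 splits gave as many genes as the real 2 (highest other 0), in females 1 of 10 (real 2, highest other 1) and between control sexes 1 of 10 (real 2, highest other 0), and 10 splits are too few for a share below 0.05. Over both sexes 2 of 100 drawn splits gave as many as the real 4, a share below 0.05 where the sexes are relabelled independently, and the highest other split gave 73. Since replicate numbers were treated as pairing the male and female controls, the 28 splits that keep each control pair on 1 side were also counted. Of these, 2 gave as many as the real 4, so chance is not excluded if that assumed pairing holds. The other of these 2, with 6570 genes, put the 6 arrays with the ganglion signal on 1 side. Counts that far above the real one point to a structure of the samples. The split with 73 genes put 5 of the 6 arrays with the ganglion signal on 1 side. It differs from the split with 6570 genes only in that female control 1 and female TCDD 1 changed sides. A further 7 splits with 5 of these arrays on 1 side gave 0 genes, but 0 of the other drawn splits put the same arrays together. The part of the ganglion arrays in the 73 thus stays open. For the difference between sexes the real count was 0, so that 100 of 100 splits gave at least as many by construction (highest other 4), and nothing follows on chance.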

How the results depend on the processing

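The ganglion marker mean as a covariate, the fits without the 6 arrays with the ganglion signal and the fits within a slide were chosen after the arrays were seen, and the other alternatives were planned. Over all alternatives the fitted log2 difference over both sexes stayed between 3.82 and 6.30 for Ahrr, 2.28 and 5.85 for Cyp1a1, 0.74 and 1.39 for Nqo1, and 1.67 and 2.21 for Ihh, and between male and female controls it stayed between -3.58 and -0.56 for LOC680227 and between -0.82 and -0.64 for Eif2s3. In males the gene count of 2 became 1 with normexp, 1 with probes well above background on all 12 arrays, 4 with eBayes without trend, 6543 with array quality weights, 1 with only the groups of the comparison, 27 with slide as a fixed block (23 higher, 4 lower), 0 without variance moderation, 4 with the covariate, 0 without the 6 arrays and 277 within slide 1 (72 higher, 205 lower). In females the count of 2 became 1 with normexp, 1 with probes well above background on all 12 arrays, 0 without variance moderation, 0 without the 6 arrays and 0 within slide 3. Over both sexes the count of 4 became 197 with array quality weights (99 higher, 98 lower), 14 with slide as a fixed block, 2 with the replicate block of the number (Nqo1 and Ihh lost), 11 with the covariate and 0 without the 6 arrays. Leaving out 1 replicate gave 4 to 9 over both sexes, 2 to 3 in males, 2 to 3 in females, 0 to 0 for the difference between sexes and 2 to 2 between controls. The difference between sexes went from 0 to 6 with slide as a fixed block. Between controls the count of 2 became 1 with normexp, 1 with probes well above background on all 12 arrays, 0 with only the groups of the comparison, 10 with slide as a fixed block, 0 with the replicate block of treatment and number, 0 without variance moderation and 0 without the 6 arrays. Limiting the genes to probes well above background on all 12 arrays removes Cyp1a1 and LOC680227 by construction. The normexp offset shrinks differences of dim signals by construction, and for the other alternatives the cause was not tested. The counts moved by no more than 1.5 times with quantile normalization, median centring, the authors' value table, no filter on dim probes, outlier spots kept, the mean of the probes of a gene, each probe tested and slide as a random block. With slide as a fixed block the median of all genes in males was -0.104. Fewer arrays were fitted without the 6 arrays, with groups of 2, 1, 2 and 1, and a lone array was taken to vary like the other groups.

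The list counts of 6 in males, 13 in females, 5 over both sexes, 7 for the difference and 3 between controls became 0, 0, 0, 0 and 0 with an estimated correlation and 0, 0, 1, 0 and 1 with fry. Slide as a fixed block gave 10, 5, 9 and 11 for males, females, both sexes and controls, the covariate gave 2 in males, and the fit without the 6 arrays gave 10 over both sexes. Leaving out 1 replicate gave 2 to 8 lists in males, 7 to 14 in females, 3 to 8 over both sexes, 5 to 11 for the difference and 3 to 4 between controls. Among the lists that camera called in a comparison, some means changed sign or direction. Those of cholesterol synthesis genes did so without the 6 arrays (-0.0142 in males and -0.0683 over both sexes) and with the covariate over both sexes (0.0076). In males without the 6 arrays, those of gonadotrope genes (0.0873) and mesenchyme and fibroblast markers (0.073) turned. With slide as a fixed block, the female means turned for corticotrope and melanotrope genes (0.0377), erythroid markers (-0.39), immune cell markers (-0.26), endothelial markers (-0.059) and Nrf2 antioxidant genes (-0.1051). The same block turned the mean of ribosomal protein genes between controls (0.0779). Lists that were not called are left out here, although skeletal muscle markers in females also turned with this block (0.05). Without the 6 arrays the difference of the effect between sexes turned for skeletal muscle markers (0.0784), and leaving out 1 female array turned the female means of erythroid markers, immune cell markers and Nrf2 antioxidant genes. The cause was not tested. Same-numbered control and exposed arrays correlated at -0.22, 0.34 and 0.44 in males and -0.48, -0.70 and -0.37 in females, and exposed males and females at 0.65, -0.09 and -0.39, so these arrays share only a number, and the replicate block of the number moved no other gene count by over 1.5 times. The signal over background limits Cyp1a1, LOC680227, Gpr97, AA926063 and Stk32a, each not well above background in at least 1 group, so their fitted values are no measured differences. Background also limits the difference of Ghrhr, through male TCDD 1 and female TCDD 2. Normexp made 29 of 82 named gene differences smaller by over 1.5 times and 0 larger, with 0.10 for Gpr97, -0.24 for AA926063 and 0.28 for Stk32a. Its offset of 50 acts in this direction by construction.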

Other observations

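The level of forebrain neuron markers, a list written after the arrays were seen, also differed between arrays. The mean of 11 measured markers was highest in female TCDD 3 (-2.25), male TCDD 1 (-2.48) and female TCDD 2 (-2.97), and lay between -4.26 and -3.48 in the controls. The remaining exposed arrays lay within the control range, at -3.56 in male TCDD 2, -3.91 in male TCDD 3 and -3.79 in female TCDD 1.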
